A study of Drosophila melanogaster with 4 samples.

How the data were processed

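The series holds 4 libraries from Drosophila melanogaster embryos of the labelled stage 0-8. Chromatin immunoprecipitation followed by sequencing (ChIP-seq) enriches DNA fragments that were crosslinked to a protein, and input DNA is the same kind of chromatin without that enrichment. The labels place 2 libraries in the ChIP group and 2 in the input group, numbered as replicates within each group. Nothing in the labels states whether the replicates came from separate embryo collections.

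The labels disagree about the protein. The title of every sample names TCF, the antibody field of the ChIP samples gives tango as its target, and the strain field gives Hr46-GFP, with a transgene that carries the Hr46 coding region. Tango is a basic helix-loop-helix PAS protein (the fly ARNT), TCF is the DNA-binding partner of armadillo in Wingless signalling, and Hr46 is a nuclear receptor. The extraction protocol also names another fly stock and another egg-collection window than the stage field. For this reason the peaks are described below without assigning them to one of the 3 proteins.

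The data are 1 peak list for the whole series. The authors wrote a score for each peak, with no unit or scale, together with its first and last base; per the file headers the coordinates are on FlyBase release 5, and the list names MACS as its source. MACS2, BWA, CASAVA 1.7.0.2, CASAVA 1.7.0.3 and the build BDGP5 appear in the submitters' processing notes, without their roles. The threshold for a peak, the treatment of reads that map to several places, how the input entered the score and whether the replicates were pooled before calling are not given in the sources used here. How reads from repeated DNA were placed bears directly on the counts on unplaced scaffolds. No values per library were used, so read depth is unknown, no value has an error between replicates, and no test compares ChIP with input libraries. All p-values below describe the arrangement of peaks in this list. Peaks are not biological replicates.

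Coordinates are 1-based. Peak width is last base minus first base plus 1, and the midpoint stands for the position, since the list gives no summit. The sequences were grouped as the 6 chromosome arms (2L, 2R, 3L, 3R, 4 and X), the heterochromatic scaffolds assigned to a chromosome (names ending in Het), the unplaced scaffold collections U and Uextra, and the mitochondrial genome. Arm lengths of release 5 were not used here, so densities refer to the span between the outermost peaks of each sequence. Clustering was tested by the median distance between neighbouring midpoints, and by the share of neighbours within 5 kb, against 1000 uniform placements of the same number of peaks between the outermost ones on each arm, one-sided. Dense regions are windows of 100 kb, ranked by peak number and then by summed score. Score and width were related by Pearson's r and Spearman's rho across peaks, with two-sided permutation p-values from 100000 resamples and Benjamini-Hochberg adjustment over the 2 coefficients in 4 sets of peaks. The 10 peaks with the highest scores are named by position. These designs, the stricter peak sets and the merging of peaks closer than 5 kb were fixed before the data were examined. The share of neighbours within 5 kb, the grouping of arm peaks into runs (peaks at most 500 bp apart, with 5 or more peaks in a run), the score limit of 100 for strong peaks and the width profile along Uextra were chosen after the data were seen.

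On simulated data with the 1668 arm peaks, even placement was called clustered in 6 of 100 simulations by either statistic. With 10% of the peaks moved into clusters, the median distance called 4 of 100 simulations and the share within 5 kb called 55 of 100. With 30% moved, they called 20 and 100 of 100. With 60% moved, both called 100 of 100. Clustering in the smaller sets of arm peaks was not simulated. The score and width test called 5 of 100 simulations with shuffled scores and 100 of 100 with a relation added. The comparison of run layouts called 6 of 100 shuffled sets. It called 100 of 100 sets in which copies of one layout, slightly shifted and some reversed, replaced part of the 32 runs. Looser copies were not simulated. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

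The design also planned 4 results that need release 5 sequence or gene annotation: the position of peaks relative to genes, fixed gene lists, motif content and scores at promoters. A genome of that build was not used here, and the gene table at hand is on a later release, so those results were left out and no gene is named from a peak's coordinates.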

Results

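The series profiled chromatin of whole Drosophila embryos with 2 ChIP and 2 input libraries, and its question was where in the genome the immunoprecipitated protein was bound. Its labels name 3 proteins (TCF, tango and Hr46), so the target is left open here. The list held 9485 peaks that together covered 5854 kb. Peak width had a median of 559 bp (interquartile range 382 to 677 bp) and ran from 201 to 5856 bp. Scores are the peak caller's own values as the authors gave them, on an unstated scale, and ran from 6.41 to 871.37 with a median of 42.26. Without values per library there is no replicate error behind any number in this section, and read depth is unknown.

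Most peaks did not lie on the chromosome arms. Uextra, a collection of small scaffolds that were never placed on a chromosome, held 6998 peaks, or 73.8% of the list, and U, the other collection of unplaced scaffolds, held 523 peaks (5.51%). The 6 arms held 1668 peaks (17.6%), the heterochromatic scaffolds 287 (3.03%) and the mitochondrial genome 9. Per Mb between the outermost peaks, Uextra carried 244 peaks and U carried 52.4, against 14.0 on the arms and 34.6 on the heterochromatic scaffolds. Peaks covered 13.5% of the span of Uextra and 5.43% of that of U, and 1.07% of the arms. The shares depended on the score limit. Among the 4742 highest scores, 4254 peaks lay on Uextra and 186 on the arms, and among the 1000 highest scores 780 lay on Uextra and 103 on the arms. Of the 167 peaks scoring 100 or more, Uextra held 46.7% and the arms 40.7%. Of the 51 scoring 200 or more, Uextra held 29.4% and the arms 64.7%, while 7 of the 10 highest lay on Uextra and 2 on the arms.

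Among the arms, 2L carried 379 peaks (16.7 per Mb of span), 3L 359 (14.7 per Mb), X 331 (14.8 per Mb), 3R 308 (11.1 per Mb) and 2R 278 (13.1 per Mb). The small chromosome 4 carried 13 peaks over a span of 0.735 Mb (17.7 per Mb). Once peaks closer than 5 kb were merged, the 5 long arms ranged only from 6.11 groups per Mb on 3R to 7.19 on X. With 6.57 on both 2L and 2R, 2L no longer ranked first among the long arms. Chromosome 4 had 13.6 per Mb, from 10 groups. No test of arm against arm was made, because the lengths of the arms in this release were not used.

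Score distributions differed in shape between the sequence classes. Arm peaks had a median score of 17.7 (interquartile range 12.8 to 24.2), and 85.0% of them scored under 30. Peaks on Uextra had a median of 49.9 (26.2 to 64.1) and on U of 50.1 (16.5 to 70.8), whereas the heterochromatic scaffolds had a median of 12.9 (10.7 to 16.8). Scores of 200 or more were nonetheless rarer on U and Uextra. They were reached by 33 of the 1668 arm peaks (1.98%) and by 17 of the 7521 peaks on U and Uextra (0.226%), an odds ratio of 0.112 for U and Uextra against the arms (Fisher's exact test, two-sided, p = 1.05e-13, chosen after the scores were seen).

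**Figure D1:**
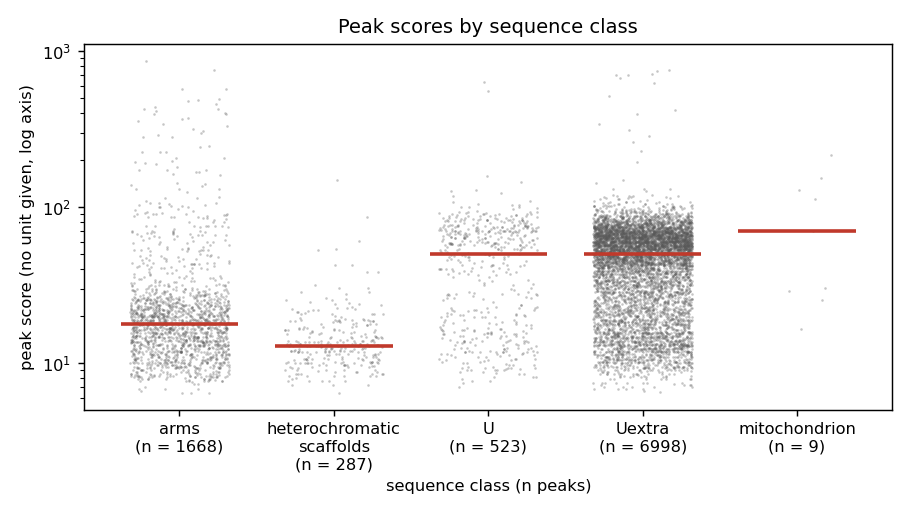
Score of every peak (log axis, no unit given by the authors) in each sequence class, with points spread sideways at random and a red line at the class median. Arm peaks have a median of 17.7 with a thin tail up to 871, while peaks on Uextra gather around a median of 49.9.

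The highest score in the list, 871.37, belonged to a 707 bp peak on 3R from 7604012 to 7604718 (release 5). Among the 10 highest, 1 further peak lay on an arm, on 3L from 18178744 to 18179363 with a score of 755.11. Of the others, 7 lay on Uextra and 1 on U. The Uextra peaks started at 6118252 (score 761.58), 13798607 (749.73), 23790137 (713.42), 2831273 (709.18), 27103588 (701.77), 21748085 (672.35) and 22939294 (625.95), and the U peak started at 9538394 (635). On the arms, the next highest were on X from 2031141 to 2031639 (576.03), on 2L from 480831 to 481335 (570.01), on 3R from 21463118 to 21463654 (494.37) and on 2R from 6158586 to 6159215 (488.54), which were named after their values were seen. The genes and annotation at these positions are not given, since annotation of this release was not used here.

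Strong arm peaks stood alone. There were 68 arm peaks with a score of 100 or more, of which 18 lay on 3L, 17 on 3R, 16 on 2L, 10 on 2R, 7 on X and 0 on 4. Their median width was 616 bp (interquartile range 528 to 710.5 bp, range 361 to 1705 bp), against 498 bp (316 to 905 bp) for all arm peaks. All 68 had no other peak within 500 bp, and the same held for 687 of the 1600 weaker arm peaks (42.9%) (Fisher's exact test, two-sided, p = 6.94e-25). Neighbouring peaks share this property, so the test counts peaks that are not independent, and it overstates the contrast. Counted as groups of peaks at most 500 bp apart, 755 of 1014 groups were single peaks, with the 68 strong peaks among them. The highest score of any arm peak with a neighbour within 500 bp was 55.88, and 140 arm peaks scored above that value. The count of strong peaks moves with its limit, from 156 peaks at 50 or more to 33 at 200 or more.

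Arm peaks as a whole were clustered. The median distance between neighbouring midpoints on the arms was 3355 bp, against a median of 49240 bp in 1000 uniform placements (central 95% from 46822 to 51506 bp), a ratio of 0.0681 (permutation test, one-sided, p = 0.001, the smallest these placements can give). Neighbours within 5 kb made up 51.9% of the distances, against 6.86% in the placements. For the 68 strong peaks no clustering was detectable. Their median distance was 1157706 bp, against 1034390 bp when placed evenly (permutation p = 0.855). None of their neighbours lay within 5 kb, but the share was also 0% in the median placement. The power of either statistic with 68 peaks was not simulated, so these values cannot exclude clustering of strong peaks. On U the ratio was 0.466 (permutation p = 0.001) and on Uextra it was 0.948 (permutation p = 0.001). Both are collections of separate scaffolds, so distances between neighbours there need not be distances along a chromosome. Peaks per 1 Mb bin of Uextra also ranged from 33 to 368, which uniform placement ignores, so these p-values do not show clustering. The arm result rested on close neighbours, since merging peaks within 5 kb left 802 groups with a ratio of 0.991 (permutation p = 0.397), although merging removes close neighbours by construction.

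Part of the clustered peaks formed runs. Taking arm peaks at most 500 bp apart together gave 1014 groups, of which 755 were single peaks and 60 held 5 or more peaks. These 60 runs contained 384 peaks, with 15 runs on 2L, 14 on 3L, 13 on 2R, 10 on X, 8 on 3R and 0 on 4. Their lengths had a median of 8.27 kb and ranged from 3.00 to 14.2 kb, and 31 of the 60 (51.7%) were between 8 and 9 kb long. That share was 11.8% of 17 runs with a gap limit of 200 bp and 58.9% of 95 runs with 1000 bp. Peaks covered 87.2% of their length. Scores inside runs had a median of 18.2 (interquartile range 14.2 to 21.9), close to the 17.7 of all arm peaks, and a highest value of 34.97. One such run on 2L, from 996956 to 1005716, held 9 peaks with a highest score of 23.33. With a gap limit of 1000 bp there were 95 runs with a median length of 8.40 kb, and with 200 bp there were 17 with a median of 7.15 kb.

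**Figure D2:**
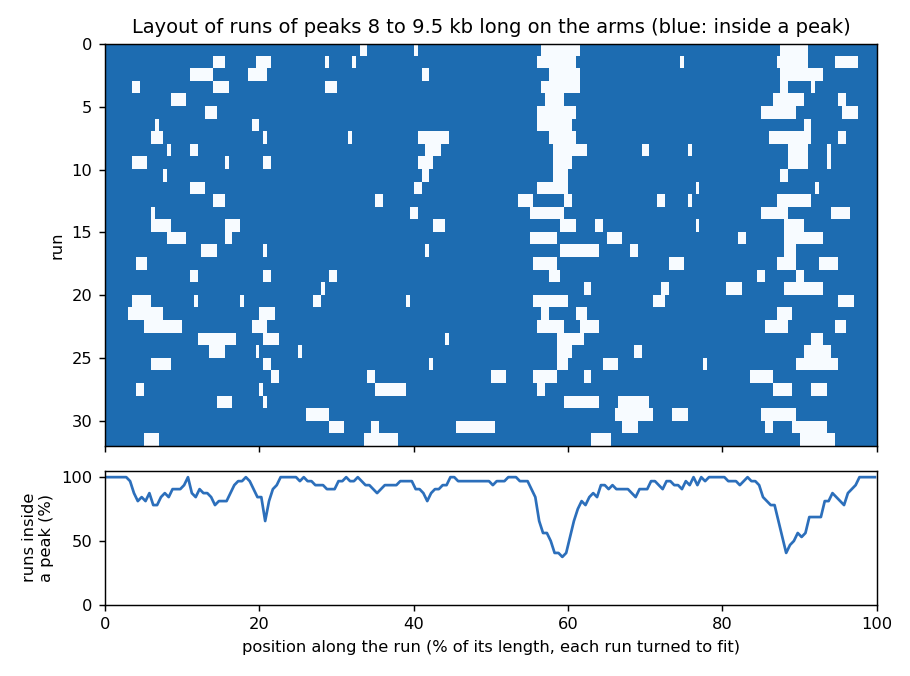
Each line is 1 of the 32 runs between 8 and 9.5 kb long on the arms, scaled to equal length and turned to the direction that fits the others better, with blue inside a peak. The curve gives the percentage of runs that lie inside a peak at each position: its median is 93.8%, and its lowest value, 37.5%, lies at 59.2% of the length.

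The 10 densest windows of 100 kb comprised 9 on Uextra and 1 on 2L. The first, on Uextra from 25100001 to 25200000, held 48 peaks with a median score of 54.2. The window on 2L from 21400001 to 21500000 also held 48 peaks, but with a median score of 13.2 and a highest score of 29.71. The window beside it, from 21500001 to 21600000, held 33 peaks. The next densest arm windows lay on 3L from 6400001 (18 peaks), on X from 13900001 (16 peaks) and on 2R from 21000001 (15 peaks).

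**Figure D3:**
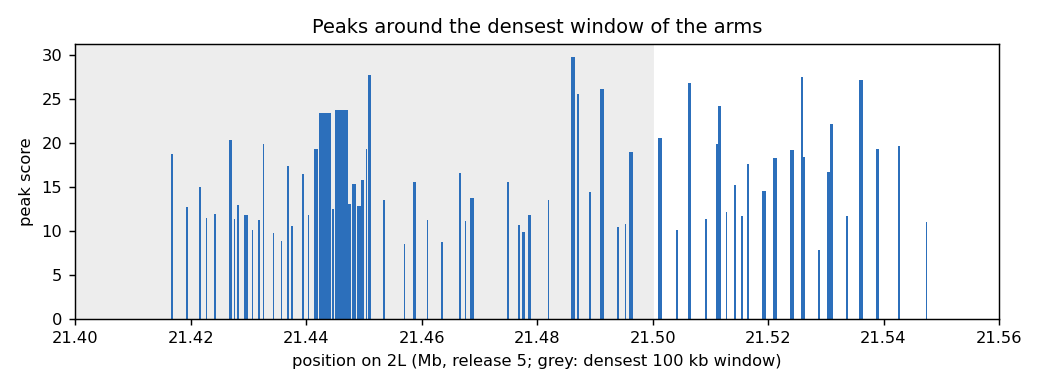
Peaks on 2L around the densest arm window (grey, 21400001 to 21500000, 48 peaks), with each bar as wide as its peak and as high as its score. The highest score in the grey window is 29.71, and peaks continue beyond its right edge.

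Wider peaks tended to have higher scores when ranks were compared. Over all 9485 peaks Spearman's rho was 0.58 and Pearson's r was 0.17 (permutation p = 1e-05 for each, the smallest 100000 resamples can give, adjusted p = 1.14e-05). Within Uextra rho was 0.67 and r was 0.43, and within U rho was 0.80 and r was 0.44, with the same p-values. On the arms rho was 0.53 with the same p-value, whereas r was 0.00428 (permutation p = 0.862, adjusted p = 0.862). The 175 arm peaks wider than 1705 bp, the greatest width among the strong peaks, had a median score of 22.6 and a highest score of 66.81. This width cut leaves out every strong peak by construction, so the absence of strong peaks from the set is not a separate result. Among the 1000 highest scores the coefficients were slightly negative, with rho at -0.0627 (permutation p = 0.0486) and r at -0.0788 (permutation p = 0.0163), both without adjustment. This set was cut on the score itself, which narrows its range, so these values do not show that the relation reverses. These coefficients are across peaks, which are not independent replicates.

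**Figure D4:**
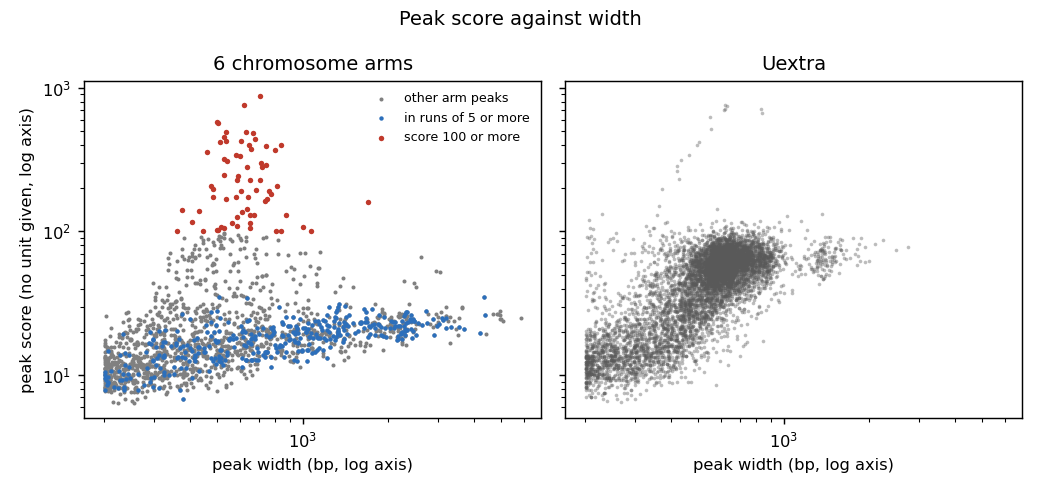
Score against width (both log axes) for peaks on the arms (left) and on Uextra (right). On the arms, the 68 peaks with a score of 100 or more (red) have a median width of 616 bp, and peaks in runs of 5 or more (blue) reach several kb with scores up to 34.97.

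On Uextra, peak width fell along the sequence. The median width was 876 bp between 2 and 3 Mb, 620 bp between 10 and 11 Mb, 561.5 bp between 20 and 21 Mb and 359.5 bp between 28 and 29 Mb, and the 95th percentile fell from 1009 to 493 bp between the first and the last of these bins. The first bins, with 33 and 49 peaks, had medians of 390 and 394 bp. Across the 6998 peaks, Spearman's rho between position and width was -0.36 (permutation p = 1e-04, the smallest 10000 resamples can give). On the 5 long arms it lay between -0.12 on 3L and 0.13 on 2R, and on U it was 0.22.

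**Figure D5:**
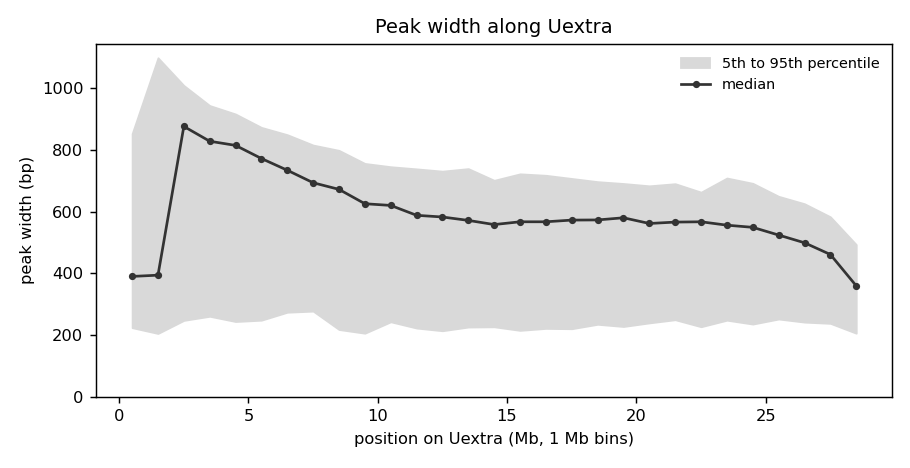
Peak width along Uextra in bins of 1 Mb, as the median (points) and the 5th to 95th percentile (grey). The median falls from 876 bp in the bin from 2 to 3 Mb to 359.5 bp in the bin from 28 to 29 Mb.

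The 9 mitochondrial peaks had a median score of 70.0, and the 4 that scored above 100 lay at 13164 to 14122 (113.28), 14264 to 15004 (153.34), 17947 to 18318 (128.36) and 18370 to 19577 (214.72). The heterochromatic scaffolds held 102 peaks on 2RHet, 101 on 3LHet, 63 on 3RHet, 18 on 2LHet, 2 on XHet and 1 on YHet. Only 1 of these 287 peaks, on 2RHet, scored 100 or more (148.94).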

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

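No paired analysis was possible because the ChIP and input replicates share numbers but the peaks come from 1 list of the whole series, and for the same reason no replicate could be left out. The score limits, gap limits and the sets without U and Uextra or of strong peaks alone were chosen after the data were seen. The share of peaks on the arms, 17.6% in the full list, was 3.92% among the 4742 highest scores, 10.3% among the 1000 highest, 29.3% after merging within 5 kb, 40.7% at scores of 100 or more, 64.7% at 200 or more and 84.9% without U and Uextra; with the 6 arms alone it has no meaning. The clustering ratio on the arms, 0.0681, became 0.938 among the 4742 highest (permutation p = 0.209), 1.05 among the 1000 highest (p = 0.695), 0.991 after merging within 5 kb (p = 0.397) and 1.12 for scores of 100 or more (p = 0.855). The share of neighbours within 5 kb was the more sensitive statistic in simulations with 30% of peaks moved. Among the 4742 highest it was 2.23%, against 0.559% in the placements (permutation p = 0.0559). Among the 1000 highest it was 0%, as in the median placement. Merging removes close neighbours by construction, and the stricter sets keep few arm peaks (184 and 103 used); placement over whole arms was not run. The densest window, on Uextra with 48 peaks, was a different one in every setting: on U from 8100001 with 12 peaks among the 1000 highest, on Uextra from 2300001 with 9 after merging, from 19500001 with 28 in windows of 50 kb and from 25900001 with 34 among the 4742 highest. With the 6 arms alone, or without U and Uextra, it was the one on 2L, also with 48. Spearman's rho of score and width, 0.58, was -0.0627 among the 1000 highest, and Pearson's r, 0.17, was -0.0788 there; among the 4742 highest rho was 0.18 and r 0.033 (permutation p = 0.0243), and on log2 values r was 0.52. The cause was not tested. Without U and Uextra r was 0.02 (p = 0.336) and rho 0.56. The 68 strong arm peaks numbered 156 at a limit of 50 and 33 at 200. The 60 runs numbered 17 with a gap limit of 200 bp, 95 with 1000 bp and 0 in either stricter set, and 59 without the densest window on 2L.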

Other observations

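The comparison of run layouts with rotated ones, and the shares of runs and of strong peaks near centromeres, were set before those values were computed, on runs and score limits already chosen from the data. All other tests in this part were chosen after their result, or the pattern they concern, was seen. Single arm peaks scoring under 100 were frequent near centromeres, mainly on 2L. Of the single peaks scoring under 100 on the 5 long arms, 133 of 678 (19.6%, exact 95% interval 16.7 to 22.8%) lay in the 10% of their arm's span nearest the centromere, where even spread gives 10% (exact binomial test, two-sided, p = 6.98e-14). Of the 68 strong peaks, 4 lay there (5.88%, interval 1.63 to 14.4%), a lower share than among the weak single peaks (Fisher's exact test, two-sided, p = 0.003). This difference rested on 2L: without that arm the shares were 4 of 52 and 72 of 524 (Fisher's exact p = 0.284), and without its densest window p was 0.0209. Of the 5 arms, only 2L passed the exact binomial test after Benjamini-Hochberg adjustment over the arms (61 of 154, adjusted p = 1.75e-21). The counts were 19 of 113 on 2R and 22 of 138 on 3L (exact p = 0.0262 and 0.0316, adjusted p = 0.0526 for both), 18 of 139 on 3R (adjusted p = 0.32) and 13 of 134 on X. Peaks of a dense stretch are not independent, so these tests overstate the evidence and the interval for the weak peaks is too narrow. Without the densest window on 2L the share was 16.3% (106 of 651). The window beside it, from 21500001 to 21600000 with 33 arm peaks of any kind, was kept. Values without the densest window are therefore not free of the whole dense block.

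Runs of adjoining peaks on the arms may be copies of one dispersed repeat. The layouts of peaks and gaps in the 32 runs between 8 and 9.5 kb long had a mean pairwise correlation of 0.19 in the better of both directions, above the highest value of 1000 sets with rotated layouts (0.0951) and of 1000 sets with shuffled order of peaks and gaps (0.0997). Run lengths were also more alike than in rebuilt runs. Of the 60 runs, 51.7% were 8 to 9 kb long, against a median of 11.7% and a highest value of 28.3% in 1000 sets rebuilt from randomly drawn peaks and gaps. The share was 11.8% of 17 runs with a gap limit of 200 bp and 58.9% of 95 runs with 1000 bp. The class of 8 to 9 kb was picked from the observed lengths, so this comparison cannot decide against separate sites that happen to lie close together. DNA that gathers next to centromeres predicted a share of runs above 10% in the 10% of the span nearest the centromere. The share was 8.33%, which met the criterion set beforehand against it (at most 10%). The interval, from 2.76 to 18.4%, also holds higher shares, so this explanation is left open. Whether the immunoprecipitated protein bound such a repeat, or its copies were more abundant in ChIP than in input DNA, needs coverage per library, and no biological explanation was tested.

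Most peaks lay on U and Uextra, and their mix of scores differed from that on the arms. Of the peaks on U and Uextra, 0.226% scored 200 or more against 1.98% on the arms, while their median score was higher, at 49.9 against 17.7. The limit of 200 was chosen after the scores were seen, so this describes the list and does not bear on why peaks lie there. DNA of those contigs may have been more abundant in ChIP than in input: peaks covered 11.4% of the span of U and Uextra against 1.07% of the arms, but without coverage per library this cannot be told apart from binding within repeats. Peak ends set by contig ends on Uextra are a candidate explanation for the fall of width with position (rho -0.36), but the contig ends were not used here. On U, the other collection of unplaced scaffolds, rho had the opposite sign (0.22). On 3L (rho -0.12) and 2R (rho 0.13) width also varied with position beyond the limit of 0.1 set for the arms (permutation p = 0.0291 and 0.0258, without adjustment). How reads with several matches were placed stays open as well. No biological explanation was tested.

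The dense block of peaks on 2L may reflect a tandem repeat, but the tests disagree. The first test, for midpoints that recur at 1 phase of a unit of 3 to 8 kb, argues against such a unit. The highest Rayleigh power over those periods was 2.00, below the median of 3.92 for uniform placements. Only after that result was a further test tried, over lags of 2 to 8 kb. In that range the covered stretches of the 100 kb window had their highest autocorrelation, 0.268, at a lag of 5.04 kb. It was above the highest value of 1000 shuffled layouts, 0.236 (permutation p = 0.001, the smallest these can give). Another maximum, 0.257, lay at 2480 bp, which is shorter than the periods searched in the first test. The window held 2.42 peaks per 5.04 kb, so that peaks at several phases of a unit could cancel in the first test, which was not checked by simulation. The tandem histone gene array of this arm is a candidate source, but its position in this release was not used here, and no biological explanation was tested.

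Which of the 3 proteins named in the labels was immunoprecipitated was not tested. The predictions written beforehand concerned the tango, TCF and nuclear receptor core motifs at the peaks, and they need release 5 sequence, which was not used here.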
